A study of Mus musculus with 13 samples.

How the data were processed

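Expression arrays were run on total RNA from 1 brain hemisphere of each of 13 male mice of the inbred strain C3HeB/FeJ. Per the labels, 6 mice ate pellets with 1% creatine for 6 months and 7 mice ate pellets of equal calories without creatine, from an age of 10 to 12 weeks. The arrays are labelled as biological replicates and were treated as separate mice. Biotin-labelled cRNA was made from 3 µg of RNA, per the labels.

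The deposited table gives 1 intensity per probe set and array for 45101 probe sets, on a linear scale in whole numbers with zeros. On every array the mean after removing the highest and lowest 2% of probe sets was 150.05, while the medians ran from 37 to 45 and the upper quartiles also differed. Intensities deposited by the authors thus have the form of a global scaling of each array to one target. The submitters' processing notes name RMA only, a method that returns log2 values, usually with equal quantiles, so the values contradict it; the scaling tool, its version and its target are not given in the sources used here. No second scaling was applied in the reported results.

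An offset of 16 was added and log2 taken, because zeros have no logarithm. The 64 control probe sets were set aside, and 45037 probe sets were tested without a filter on dim ones. Of these, 34945 carried 1 gene symbol, 932 carried several and 9160 had none listed here; the named ones stand for 18193 genes. Symbols came from the probe table supplied with the series, updated through the Entrez ID where the gene reference held it (34741 probe sets). No coordinates are given, since the table names no genome build.

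Differences between creatine-fed and untreated mice were fitted per probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 2-sided and without covariates, and p was adjusted by Benjamini-Hochberg over all 45037 probe sets with a threshold of 0.05. For 42 gene lists with at least 4 measured members, each gene was represented by its brightest probe set, and camera from limma tested whether the list shifted against other genes, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Beside it stand camera with a correlation estimated per list, the rotation test fry, which asks whether members move on balance in 1 direction or, in its mixed form, in either direction, and an exact permutation test of the per-array list mean over all 1716 splits of 6 against 7. Members were also adjusted over the list alone. Principal components used centred, unscaled probe sets, and their scores, like the 3'/5' ratios of the control probe sets, were compared by exact permutation, 2-sided.

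The groups, tests, thresholds, gene lists, alternatives to try and the rule for naming genes were fixed before the data were examined. Genes named are the measured members of the creatine list; the 12 genes per direction with the largest change among those past the threshold, with open places filled by the smallest unadjusted p and given as not passed; up to 4 members of each list with the smallest unadjusted p; and genes that check the labelled sex. One further probe set, a few list members and Tia1 were named after their values were seen, as stated beside them.

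Alternatives fixed at that point were the 22519 probe sets with the higher mean over the 13 arrays, quantile normalization, centring each array on its median, covariates for the 3'/5' ratio or the first residual component, array weights, the replicate number as a block, leaving out each mouse, eBayes with trend and robust, an exact rank-sum test, other thresholds, 1 probe set per gene, and other list tests. Added after the data were seen were offsets of 1 and 50, covariates for cerebellar, olfactory bulb or brainstem markers, and leaving out a pair of arrays that stood apart. The offset of 16 was not named in the plan either, which gave log2 of the value alone. Nor did the plan name tests of components beyond the first. The fit was also repeated on 100 drawn splits of the 13 mice, the real one among them.

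The procedure was tested on simulated data of 45037 probe sets at these group sizes, with changes planted in some of them. It recovered 41% of 100 planted log2 changes of 0.5 and 94% of 100 planted changes of 1, and 5.59% of its calls were false. Simulated probe sets were independent and normally distributed, without outlying mice, so these rates need not hold for the real arrays. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.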

Results

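Gene expression was measured in 1 brain hemisphere from each of 6 male mice fed creatine for 6 months and 7 untreated male mice of the same strain. Creatine is a compound that cells use to buffer their ATP supply through creatine kinases. Each array gave intensities for 45101 probe sets, with an array median between 37 and 45. Pearson's r between pairs of arrays, across probe sets, ran from 0.975 to 0.987; probe sets are not independent replicates. No pair of arrays shared the same value in more than 5.68% of probe sets.

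The comparison of creatine-fed with untreated mice asks which transcripts of the hemisphere differ after creatine feeding. Mef2c, a transcription factor of neurons and muscle, rose at probe set 1451506_at, from 509 ± 60.6 (SD, n = 7) in untreated mice to 840 ± 107 (SD, n = 6) in creatine-fed mice, a log2 difference of 0.71 ± 0.10 (SE, adjusted p = 0.0419). Kdm5a, a histone demethylase, rose at 1452360_a_at from 88.1 ± 6.23 to 130 ± 8.0 (log2 difference 0.49 ± 0.06, adjusted p = 0.0402). Tcl1b3, a member of the Tcl1 family of signalling cofactors, fell at 1420570_x_at from 936 ± 102 to 584 ± 29.4 (log2 difference -0.66 ± 0.08, adjusted p = 0.034). Probe set 1419458_at, which has no gene symbol listed here and was chosen after its values were seen, rose from 39.9 ± 6.62 to 73.3 ± 9.27 (log2 difference 0.68 ± 0.09, adjusted p = 0.0419). For each of these, all 6 creatine-fed mice lay beyond every untreated mouse.

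**Figure D1:**
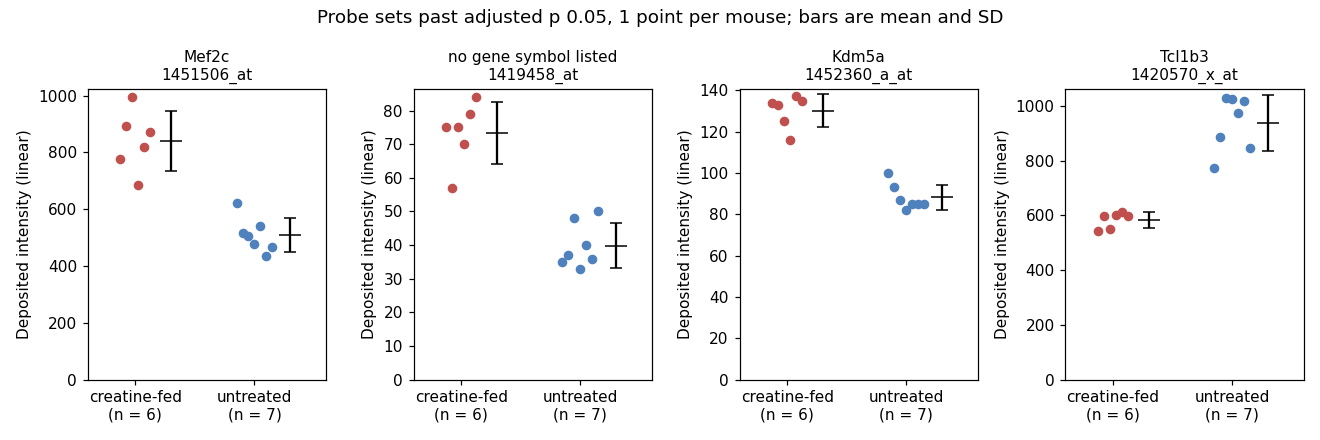
Deposited intensity (linear scale, from 0) of the 4 probe sets past an adjusted p of 0.05, 1 panel each, with 1 point per mouse for 6 creatine-fed and 7 untreated mice and bars for mean and SD. In every panel the groups do not overlap, as for Mef2c with means of 840 and 509.

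These 4 probe sets, 3 higher and 1 lower, were all that passed among 45037. All 5 probe sets of Mef2c had higher means in creatine-fed mice, with log2 differences of 0.30 at 1421027_a_at, 0.25 at 1424852_at, 0.51 at 1421028_a_at and 0.12 at 1451507_at, which did not pass. Kdm5a did not move together: its brightest probe set, 1437105_at, read 198 ± 31.3 and 197 ± 20.8 in creatine-fed and untreated mice. The suffix of the Tcl1b3 probe set marks probes that can also match other transcripts.

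The count of called probe sets varied with the settings. Among the 22519 brighter probe sets, a choice fixed beforehand, 138 passed, 71 higher and 67 lower, and the 4 above were among them. They stand for 107 genes where 1 symbol was listed. This choice changed both the number of tests and limma's pooled variance. With eBayes set to trend and robust the count was 161, with the first residual component as a covariate 96, and with an offset of 50 in place of 16 it was 36. That component comes from residuals of the fit on group, so it cannot change the log2 differences, only their errors. The count was 0 with an offset of 1, with the cerebellar and olfactory bulb covariates and by an exact rank-sum test. The smallest adjusted p of the rank-sum test was 0.208, and 4760 probe sets had an unadjusted p under 0.05, where limma gave 5345. At these group sizes ranks could pass none here, because too few probe sets, 252, had groups that did not overlap. The rank-sum count therefore does not bear on the 4 above. Limma called 0 without creatine-fed replicate 3 or 5 or without untreated replicate 2, 3, 4, 5 or 6, and 2 without untreated replicate 7.

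Of the 24 genes with the smallest p, 12 per direction, 16 were among the 22519 brighter probe sets and all 16 passed there, 11 higher and 5 lower. The 24 were picked by p in these same arrays. Passing there, or the side of the untreated mean on which each mouse lay, is therefore no separate support. Beyond Mef2c, Kdm5a and Tcl1b3, none passed over all probe sets. Atp8a1, a phospholipid flippase, read 1646 ± 190 against 1099 ± 110 at 1423597_at (log2 difference 0.57, adjusted p = 0.0708). It was higher at 6 of its 7 probe sets, 3 of them at an unadjusted p under 0.05, though 1433827_at read 1285 against 1283. Slc1a2, the main glutamate transporter of astrocytes, read 1275 ± 216 against 715 ± 168 at 1439940_at (0.83, adjusted p = 0.125), and was higher at 4 of its 5 probe sets, 3 of them at an unadjusted p under 0.05, while the brightest, 1438194_at, differed by -0.01. The other genes with a probe set of higher mean were Mmp16, a membrane-bound metalloproteinase (0.50 at its brightest probe set), A830010M20Rik (0.45 at 1438565_at), the carboxypeptidase Cpd (0.47 at 1418018_at), Secisbp2l (0.61 at 1456120_at), Ush1c (0.60, but dim at 17.3 against 5.86), the Rap regulator Sipa1l1 (0.44 at 1434222_at), Zfp644 (0.62 at 1436985_at) and Wdr33, a factor of mRNA polyadenylation (0.44 at 1456488_at), with adjusted p from 0.0823 to 0.126. All 6 creatine-fed mice lay above the untreated mean for each. At their brightest probe sets Secisbp2l differed by -0.08, Wdr33 by 0.07, Cpd by 0.11, Sipa1l1 by 0.12 and A830010M20Rik by 0.16, and other probe sets of Zfp644, 1429623_at and 1419984_s_at, by -0.01 and 0.02.

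On the lower side, Creb1, a transcription factor of activity-dependent gene expression, read 273 ± 13.9 against 371 ± 22.9 at 1428755_at (log2 difference -0.42, adjusted p = 0.0561). The other 5 of its 6 probe sets went the other way, 3 of them at an unadjusted p under 0.05, the brightest, 1452901_at, reading 512 ± 32.1 against 432 ± 40.6 (0.24, adjusted p = 0.244). Wsb1, a ubiquitin ligase subunit, read 472 ± 54.5 against 659 ± 37.7 (-0.47, adjusted p = 0.0802). Lower means at 1 probe set were also seen for Muc20 (-0.70), Mapkapk3 (-0.65), the actin filament capping protein Tmod3 at 1423088_at (-0.44), Akp3 (-0.77), the tight junction protein Cldn18 (-0.74), Tpte (-0.93), Senp8 at 1438102_at (-0.56), Tsc22d1 at 1435952_at (-0.56) and Igsf5 (-0.56), with adjusted p from 0.0561 to 0.118. At their brightest probe sets Tmod3 differed by 0.07, Senp8 by 0.10 and Tsc22d1 by -0.05. Of these, Muc20, Akp3, Cldn18, Tpte and Igsf5 were dim in both groups, with means of 30.6, 18.1, 18.1, 32.7 and 24.4 in untreated mice, under the array medians. All 6 creatine-fed mice lay below the untreated mean for each gene of this paragraph at the probe set that was lower.

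At an unadjusted p under 0.05, 5345 probe sets differed where chance gives 2252 if probe sets were independent, and the highest of 99 other splits of the mice gave 4552; at an unadjusted p under 0.001, 267 did where chance gives 45. Of the 5345, 1878 were higher and 3467 lower, which is 35.1% higher. The balance moved with scaling, to 48.6% higher after quantile normalization and 63.9% after centring each array on its median, so no overall direction is given. In 252 probe sets the groups did not overlap, 0.560% of those tested, where chance gives 0.117%.

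Genes that make, carry and use creatine were not called. Means of all 8 measured members were lower in creatine-fed mice, or of 6 of the 8 after centring each array on its median, where Slc6a8 and Ckmt1 turned higher. Ckb, the brain cytosolic creatine kinase, read 5147 ± 293 (SD, n = 6) against 5519 ± 197 (SD, n = 7), a log2 difference of -0.10. Slc6a8, the creatine transporter, read 652.5 ± 45.01 against 664 ± 26.6 (-0.03), and Ckmt1, a mitochondrial creatine kinase, read 754 ± 66.5 against 769 ± 27.0 (-0.03). Gatm and Gamt, the enzymes of creatine synthesis, differed by -0.07 and -0.06, Gatm reading 340 ± 23.0 against 358 ± 31.4. Ckm, the muscle creatine kinase, was dim, at 13 ± 8.07 against 31.3 ± 15.6, with the widest log2 difference of the list, -0.68 ± 0.22 (SE, adjusted p = 0.255 over all probe sets and 0.0634 adjusted over the list alone). Slc16a12 and Ckmt2, also dim, differed by -0.23 and -0.15. No member passed over all probe sets or adjusted over the list alone.

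As a set the 8 creatine genes had a camera adjusted p of 0.123 (median log2 difference -0.08). The exact permutation test of the list mean per array gave p = 0.00524 and 0.122 after adjustment over 42 lists. The list passed with the 3'/5' ratio as a covariate (adjusted p = 0.0342) and with the mean of all probe sets per gene (adjusted p = 0.0172), both at camera's preset correlation; an estimated one was run only with all else as reported, where adjusted p was 0.435.

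Markers of the layers of the cerebral cortex and genes induced by neuronal activity stood higher in creatine-fed mice against other genes. Of 19 cortex layer markers 18 had higher means (median log2 difference 0.09, camera adjusted p = 1.87e-05; adjusted p = 0.435 with an estimated correlation). Adjusted over the list alone 4 of them rose and none fell, and no member's brightest probe set passed over all probe sets. They were Lmo4, a LIM-domain transcriptional regulator (762 ± 75.7 against 621 ± 41.2, log2 difference 0.29), Mef2c at its brightest probe set (2315 ± 88.7 against 1894 ± 221, 0.30), Ccn3, a secreted matrix protein (978 ± 109 against 794 ± 84.8, 0.30), and Stx1a, a syntaxin of synaptic vesicle release (1607 ± 172 against 1322 ± 162, 0.28), each higher than the untreated mean in 6 of 6 mice.

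Of 24 immediate early genes, 20 had higher means (median log2 difference 0.12, camera adjusted p = 1.87e-05; adjusted p = 0.435 with an estimated correlation). No member passed over all probe sets or adjusted over the list alone. Arc, a synaptic protein made after activity, read 229 ± 73.2 against 149 ± 48.0 (log2 difference 0.57, higher than the untreated mean in 5 of 6 mice). Dusp1, a phosphatase of MAP kinases, differed by 0.30, the AP-1 member Fosl2 by 0.26 and Btg2 by 0.27. A further probe set of Btg2, 1448272_at, differed by -0.20, and 1 of the 2 probe sets of Fosl2 was lower.

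Of 28 genes of long-term potentiation and memory, 23 had higher means (median log2 difference 0.06, camera adjusted p = 0.005; adjusted p = 0.435 with an estimated correlation), and no member passed by either adjustment. The NMDA receptor subunit Grin2a differed by 0.43, Plcb1 by 0.22 and Creb1 at its brightest probe set by 0.24, while Prkaca, a catalytic subunit of protein kinase A, differed by -0.17. Among the 22519 brighter probe sets this list no longer passed (adjusted p = 0.0556), nor with the brainstem marker mean as a covariate (adjusted p = 0.16).

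Markers of dopaminergic, serotonergic and noradrenergic neurons were lower in creatine-fed mice, in 14 of 17 (median log2 difference -0.27, camera adjusted p = 0.005; adjusted p = 0.435 with an estimated correlation). En1, a homeobox gene of the midbrain and hindbrain, fell adjusted over the list alone (7.50 ± 4.37 against 17.9 ± 2.41, log2 difference -0.55, adjusted p = 0.0033), with the groups apart. The serotonin transporter Slc6a4 read 9.50 ± 4.23 against 33.0 ± 20.1 (-0.83), Tph2, the enzyme of serotonin synthesis in neurons, 13.5 ± 7.69 against 35 ± 20.7 (-0.72), and Ret 116 ± 9.89 against 145 ± 24.2 (-0.28), which did not pass. En1, Slc6a4 and Tph2 lie below the array medians, and among the 22519 brighter probe sets the list had an adjusted p of 0.0556. Brainstem markers outside these lists, chosen after these lists were seen, had a median log2 difference of -0.14 over 26 measured genes (18 lower; exact permutation p of the array mean 0.167). Of these, 22 had means under every array median in both groups.

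Oligodendrocyte and myelin markers were lower in 21 of 24 (median log2 difference -0.11, camera adjusted p = 0.00764; adjusted p = 0.704 with an estimated correlation). Mag, a myelin adhesion protein, fell adjusted over the list alone (612 ± 65.6 against 754 ± 46.5, log2 difference -0.30, adjusted p = 0.039), lower than the untreated mean in 6 of 6 mice. The myelin protein Mbp was lower at 7 of its 8 probe sets, by -0.24 at the brightest, and higher at 1425263_a_at (0.60), the myelin transcription factor Myrf by -0.36 and Cldn11 by -0.17. After centring each array on its median 17 were lower and the median was -0.06. The list then did not pass (adjusted p = 0.0506), though its mean against other genes stayed at -0.07. That mean shrank to -0.04 with the replicate number as a block (adjusted p = 0.194), -0.04 without untreated replicate 7 (0.171) and -0.03 with the brainstem marker mean as a covariate (0.404), where the list did not pass either.

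**Figure D2:**
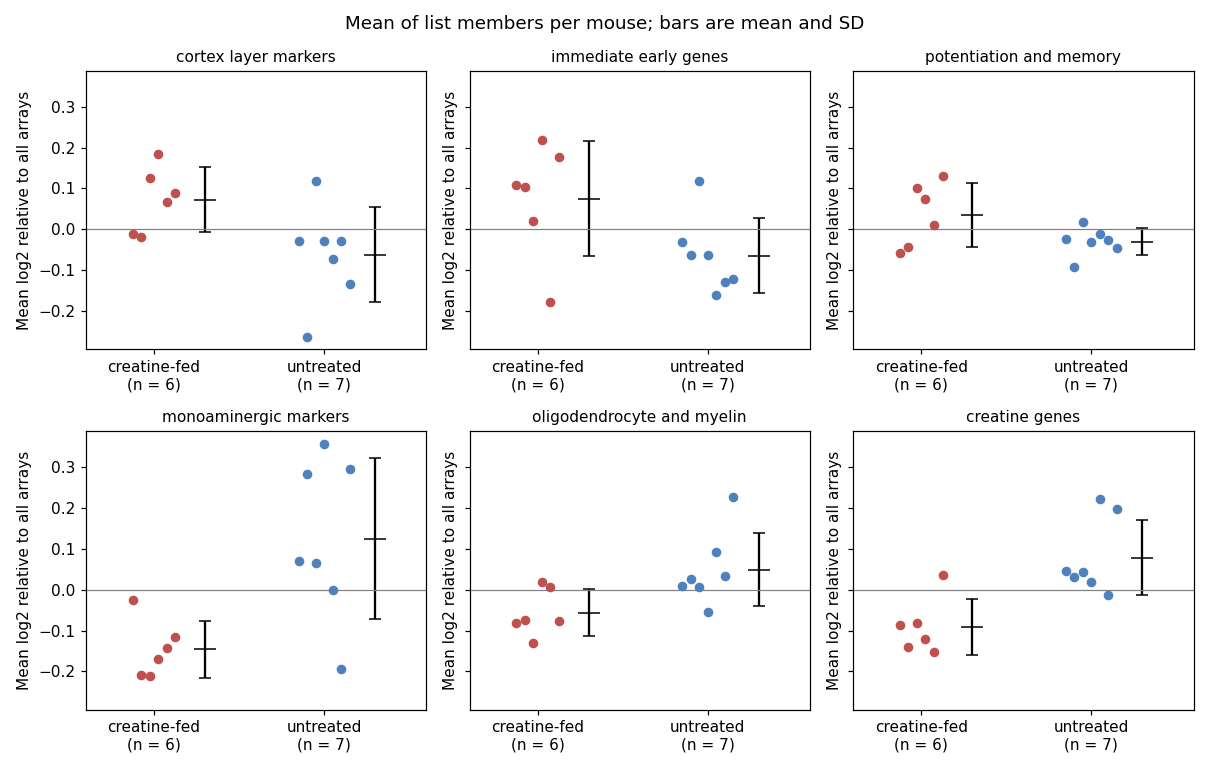
Mean log2 value of the members of 6 gene lists per mouse, relative to the mean over all 13 arrays, for 6 creatine-fed and 7 untreated mice, with bars for mean and SD. The creatine-fed mean lies higher for the cortex, immediate early and potentiation lists and lower for the monoaminergic, myelin and creatine lists, with overlap between groups in each panel.

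In all, camera called 5 of 42 lists, 3 higher and 2 lower; with an estimated correlation it called 0, fry called 1, and the exact permutation test called 0 after adjustment. The medians of the 5 lists kept their sign after quantile normalization and after centring. Nr4a2 belongs to the cortex, immediate early and monoaminergic lists. Of the 100 drawn splits of the mice, 35 gave at least 5 called lists, so chance is not excluded for them.

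Fry's 1 call was the astrocyte markers, lower on balance (adjusted p = 0.0166; camera adjusted p = 0.201): 18 of 23 had lower means, but the median of -0.03 turned to 0.02 after centring each array. Their named members, the growth factor receptor Fgfr3 (-0.21), the connexin Gjb6 (-0.20), Aldoc (-0.18) and the calcium-binding S100b (-0.22), did not pass adjusted over the list alone.

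Of 20 circadian clock genes, 3 passed adjusted over the list alone and none over all probe sets. Of the 3, the clock output factor Hlf (800 ± 55.1 against 643 ± 54.97, log2 difference 0.31) and the deubiquitinase Usp2 (503.5 ± 30.8 against 422 ± 19.9, 0.25) rose, and the clock component Per3 (301 ± 30.1 against 359 ± 23.5, -0.25) fell. A further probe set of Usp2, 1417169_at, differed by 0.06. The list had a camera adjusted p of 0.0644 and a fry mixed adjusted p of 2.21e-06, the lowest of the 42. Leaving out creatine-fed replicate 4 (adjusted p = 0.0205), 5 (0.0124) or 6 (0.0452) or untreated replicate 1 (0.038), 2 (0.046) or 5 (0.048) brought camera's circadian clock genes call past the threshold, as did array weights (0.0358) and the mean of all probe sets per gene (0.016). With the settings reported, the circadian list had an adjusted p of 0.435 with an estimated correlation, 0.225 by fry in 1 direction and 0.367 by exact permutation.

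Single members of other lists passed adjusted over the list alone. Map1b, a microtubule-associated protein of growing axons (0.49), the glucocorticoid-induced Zbtb16 (0.32), Ppargc1a, a coactivator of mitochondrial biogenesis (0.33), and the calcium pump Atp2b1 (0.23) rose, while the growth factor Vegfa (-0.37), the lipid peroxidase Gpx4 (-0.32) and the ribosomal protein Rpl11 (-0.29) fell. Ppargc1a held at 1 of its 5 probe sets: 1434100_x_at differed by -0.18 and 1437751_at by 0.00. A further probe set of Map1b, 1421851_at, read 512 against 510, and one of Zbtb16, 1419874_x_at, differed by 0.04. None of these passed over all probe sets. Map1b (adjusted p = 0.043), Vegfa (0.043), Gpx4 (0.0469), Rpl11 (0.0375) and Hlf (0.049) passed among the 22519 brighter probe sets.

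Genes of energy supply were not called as lists with the settings reported, and no direction is given for them because their medians turned with the scaling. Camera adjusted p was 0.168 for 73 subunits of oxidative phosphorylation, 0.798 for glycolysis, 0.956 for the citric acid cycle, 0.606 for mitochondrial ribosomal proteins and biogenesis and 0.339 for energy sensing, insulin and mTOR signalling. Cyc1, a subunit of complex III, read 1919 ± 198 against 2167 ± 69.4 and the glycolytic Aldoc 5871 ± 216 against 6689 ± 515, which did not pass. Oxidative phosphorylation passed with the cerebellar and olfactory bulb covariates (0.0248) and without creatine-fed replicate 2 and untreated replicate 3 together (0.03), both at the preset correlation; an estimated one, with all else as reported, gave 0.844. The ATP-consuming ion pumps had an adjusted p of 0.201.

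Antioxidant and glutathione genes (adjusted p = 0.957), apoptosis genes (0.876), proteasome subunits (0.366), autophagy and lysosome genes (0.339), heat shock and unfolded protein response genes (0.501) and cytosolic ribosomal proteins (0.123) were not called either. Of these, Gclc, the enzyme that limits glutathione synthesis, read 537 ± 62.9 against 425 ± 45.7 (0.0552 adjusted over the list alone), and -0.01 in log2 difference at 1455959_s_at. Neurotrophic factors and receptors (0.445) included Bdnf at 117 ± 10.7 against 97.6 ± 7.70 at 1422168_a_at (log2 difference 0.23, 0.0758 adjusted over the list alone), while 1422169_a_at differed by -0.06.

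Among other neuronal groups, presynaptic vesicle genes (0.123), striatal markers (0.141), hypothalamic and pituitary hormone genes (0.141), thalamic markers (0.357), hippocampal markers (0.606), GABAergic (0.916) and cholinergic neuron markers (0.957), and axon and neurite growth genes (0.507) had camera adjusted p above 0.05. Bsn, a protein of the presynaptic active zone, read 1149 ± 119 against 996 ± 32.9, and the hypothalamic peptide Hcrt 73.3 ± 10.7 against 93.0 ± 12.2. Presynaptic vesicle genes passed without creatine-fed replicate 1 (0.0266) or 5 (0.0386) and with the mean of all probe sets per gene (0.00979), and striatal markers without creatine-fed replicate 2 (0.0272) or untreated replicate 3 (0.0132). Without both of these arrays presynaptic (0.03) and striatal (0.00109) lists passed. Cytosolic ribosomal proteins passed without creatine-fed replicate 4 (0.0294) or 6 (0.0452) and with the cerebellar and olfactory bulb covariates (0.0248). All of these calls use camera's preset correlation. An estimated one, with all else as reported, gave an adjusted p of 0.782 for presynaptic genes and 0.844 for striatal markers and cytosolic ribosomal proteins.

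Markers of microglia (0.201), endothelial and mural cells (0.507), choroid plexus and ependyma (0.201), oligodendrocyte precursors (0.824), meningeal cells (0.876) and red blood cells (0.876) were not called. Nor were interferon-stimulated genes (0.141), inflammation and complement genes (0.824), cholesterol synthesis (0.201), arginine, methionine and one-carbon metabolism (0.824) or glucocorticoid-responsive genes (0.876). The neutrophil protein S100a8 read 38.8 ± 10.3 against 111 ± 79.9 (log2 difference -1.02, 0.142 adjusted over the list alone). The median of the list and the direction of camera's test differed in sign for the autophagy, axon growth, hippocampal, citric acid cycle, GABAergic, oligodendrocyte precursor, meningeal and red blood cell lists, and the mean and the test for the proteasome, mitochondrial ribosomal, antioxidant, hippocampal, citric acid cycle, GABAergic, oligodendrocyte precursor and meningeal lists.

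The labels do not state whether a hemisphere here included cerebellum and brainstem. Markers of these regions varied between mice. Untreated replicate 3 read 22 for Gabra6, a receptor subunit of cerebellar granule cells, and 18 for Cbln3, while the other untreated mice read 1248 to 2494 and 1059 to 2189. Gabra6 averaged 1422 ± 589 in creatine-fed and 1470 ± 753 in untreated mice. Cerebellar markers had a camera adjusted p of 0.357 and olfactory bulb markers 0.268, and both passed with the brainstem marker mean as a covariate (0.000284 and 0.000406). Their members move together, with estimated correlations of 0.862 and 0.610, which gave an adjusted p of 0.904 for each with all else as reported; the covariate was not run with them.

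**Figure D3:**
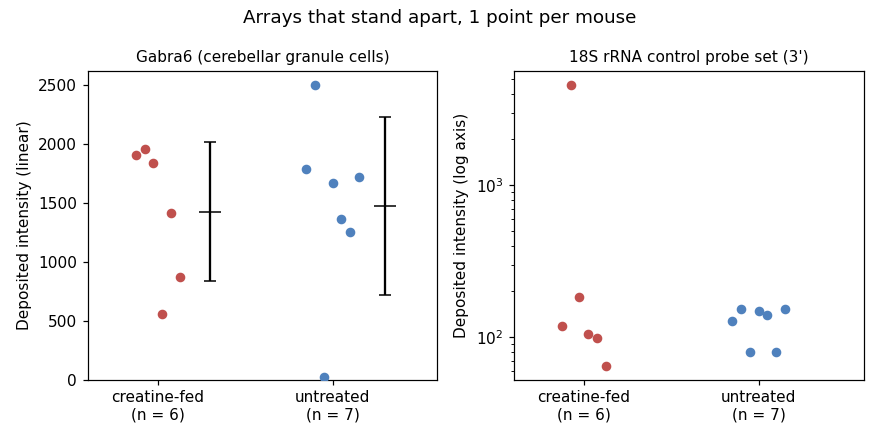
Deposited intensity of Gabra6 (linear axis from 0, with mean and SD) and of the 18S rRNA control probe set (log axis), 1 point per mouse for 6 creatine-fed and 7 untreated mice. One untreated mouse reads 22 for Gabra6 and one creatine-fed mouse reads 4569 for 18S rRNA.

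The first principal component, 14.5% of the variance among arrays, did not part the groups (difference in mean score -9.24, exact permutation p = 0.452, adjusted over 5 components 0.823). Its scores correlated with the cerebellar marker mean at -0.81. The second, 12.7%, whose test was not named in the plan, did part them. Creatine-fed mice scored 18.3 ± 12.7 and untreated mice -15.7 ± 6.60, with an exact permutation p of 0.000583, the smallest that 1716 splits can give (adjusted 0.00291). Without adjustment over components, the first had an exact permutation p under 0.05 without creatine-fed replicate 4 (-31.7, exact p = 0.00379) or untreated replicate 2 (-25.5, exact p = 0.0411), and with probe sets scaled to unit variance (86.6, exact p = 0.0466). The sign of a component is arbitrary.

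**Figure D4:**
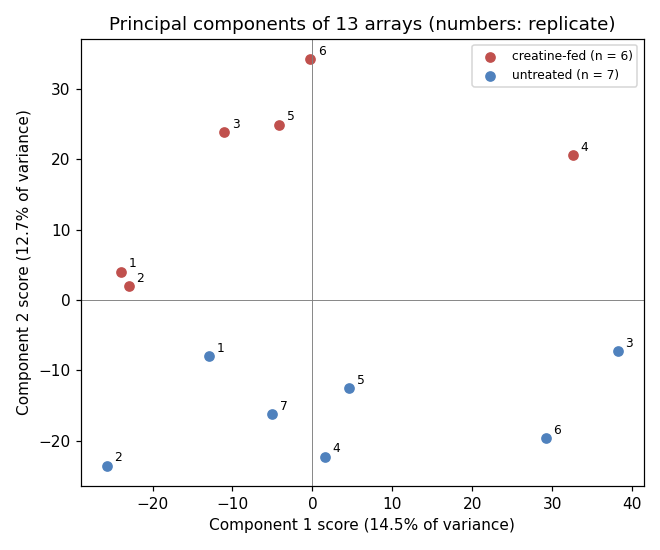
Scores of 6 creatine-fed and 7 untreated mice on the first (14.5% of variance) and second (12.7%) principal component, with the replicate number beside each point. All creatine-fed mice lie above 0 and all untreated mice below 0 on the second component.

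The 3' minus 5' log2 value of the control probe sets, a measure of RNA and labelling quality, was 0.17 ± 0.04 (SD, n = 6) in creatine-fed and 0.20 ± 0.04 (SD, n = 7) in untreated mice (exact permutation p = 0.382). For the labelled sex, the Y-linked Eif2s3y read 218 ± 21.3 and 222 ± 26.4, Kdm5d 102 ± 9.30 and 102 ± 12.7, and Uty 74.2 ± 30.5 and 59.4 ± 12.3 in creatine-fed and untreated mice, and Xist, the RNA of the inactive X chromosome, 24.3 ± 6.31 and 25.7 ± 7.85. No probe set was listed for Ddx3y in the probe table used here.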

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

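The tests with brainstem, cerebellar and olfactory bulb covariates and markers were chosen after the list results were seen, and the test of the brighter probe sets on other splits after their count was seen. The share after centring was set beside that after quantile normalization once both had been seen, and the explanation was then left open. The other tests were planned.

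Of 482 groups of values tested, 26 had an array far from the rest of its group, and chance flags about 1 in 20 groups. The cerebellar list stood apart in untreated replicate 3 at -2.23 (log2 relative to all arrays; others 0.01 to 0.76), with Gabra6 at 22, Cbln3 at 18 and Pvalb at 890. In the same mouse the thalamic list stood at -0.28 and the axon growth list at 0.0642, Suclg2 read 320, Fosl2 99 and Fmod 111. A control probe set for 18S rRNA read 4569 in creatine-fed replicate 2, against 65 to 183 in the other creatine-fed mice; these control values enter no comparison of the groups.

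The remaining values that lay far from their group are given without explanation. In creatine-fed mice, replicate 6 read 5719 for Ckb (others 4937 to 5191), 912 for Lmo4 (714 to 757) and 721 for Ppargc1a (845 to 916). Replicate 5 read 888 for Zfp644 and 1932 for Atp1b2, replicate 4 read 74 for Hk2, 421 for Gclc and 1793 for Pltp, replicate 2 read 70 for Atg7, and replicate 1 stood at -0.0798 for the citric acid cycle list. In untreated mice, replicate 2 read 626 for Ccn3 and stood at -0.0506 for the mitochondrial ribosomal list, replicate 4 read 118 for Tcf7l2, replicate 5 read 14 for Pmaip1, and replicate 7 read 414 for Fdps and 170 for Eif2s3y.

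The first pattern is the shift of 5 lists, with cortex, immediate early and potentiation genes higher and monoaminergic and myelin genes lower. Chance cannot be excluded: 35 of 100 splits of the mice gave 5 called lists or more, with 13 in the highest other split. An unequal share of cerebellum was predicted to cost calls, but 5 of 5 lists kept theirs with cerebellar and olfactory bulb covariates. This cannot decide, since calls at the preset correlation also arose in other splits and none held with an estimated one. The cerebellar covariate rests largely on untreated replicate 3, at -2.23, with the next lowest mouse at -0.75. An unequal share of cerebellum therefore stays open. Less brainstem in the hemispheres of creatine-fed mice may contribute and stays open. The labels do not state whether a hemisphere here included brainstem. Brainstem markers outside the lists had a median log2 difference of -0.139 (bootstrap 95% interval -0.263 to -0.0223). The bootstrap drew markers, not mice, so its interval does not measure spread between mice. Across mice, the exact permutation p of the markers' array mean was 0.167. With the markers' mean as a covariate 3 of 5 lists kept their call. This set and its covariate rest mostly on signal near background: 22 of the 26 markers had means under every array median in both groups, and of the other 4, Hcn2 was higher (0.28) and Glra1, Gata2 and Nefh lower (-0.33, -0.22 and -0.22); an effect of creatine stays open as well.

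The second pattern is that more probe sets were lower than higher at an unadjusted p under 0.05. The authors' scaling of each array to one trimmed mean stays open as a source: 48.6% were higher after quantile normalization, inside the 45 to 55% set beforehand for this cause, but equal quantiles pull this share towards balance by construction, and 63.9% were higher after centring each array on its median. Noise of dim probe sets stays open, since 42.4% were higher among the brighter probe sets, between the values predicted with and without it.

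The third pattern is the number of called probe sets. Chance is argued against but not excluded: 2 of 100 splits, the real one included, gave 4 or more over all probe sets, the other with 6. Among the brighter probe sets 1 of 100, the real one, gave 138, where the highest other split gave 1. That second split test was chosen after the 138 had been seen. With the 3'/5' ratio as a covariate the log2 difference of Mef2c at 1451506_at went from 0.71 to 0.66, that of Kdm5a at 1452360_a_at from 0.49 to 0.49, that of 1419458_at from 0.68 to 0.65 and that of Tcl1b3 from -0.66 to -0.63. Only Tcl1b3 kept its call. The ratio differed little between the groups (exact permutation p = 0.382), so as a covariate it could hardly move these differences. That they hardly moved therefore does not decide on RNA quality as the source. An unequal share of brain regions stays open as a source. Of the 4 probe sets, 0 kept their call with cerebellar and olfactory bulb covariates and 1 with the brainstem covariate. Lost calls alone do not decide this. A difference in handling that the control probe sets do not record and an effect of creatine were not tested and stay open.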

How the results depend on the processing

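Chosen after the data were seen were the offsets of 1 and 50, covariates from region markers and the omission of a pair of arrays. The offset of 16 was not named in the plan. The rest was planned. The exact rank-sum test called 0 probe sets (4760 at an unadjusted p under 0.05), but ranks at these group sizes could pass none here. By limma the number, 4 as reported, was 138 among the brighter probe sets, 161 with trend and robust and 96 with the first residual component as covariate. It was 13 with array weights, 21 at an adjusted p under 0.10 and 36 with offset 50. It was 2 after quantile normalization, 0 with the replicate block, 0 with offset 1 and 0 with cerebellar and olfactory bulb covariates. With the brainstem covariate it was 1, and without both doubted arrays (creatine-fed replicate 2 and untreated replicate 3) it was 2. The cause was not tested, but among the brighter probe sets both the number of tests and the pooled variance changed. The first residual component cannot move the log2 differences, since it comes from residuals of the fit on group. Leaving out 1 mouse gave 0 to 6. The number was 4 after centring (all higher, 3 of them as reported), 3 with the 3'/5' covariate, 5 with 1 probe set per gene and 4 at a fold of at least 1.2. Replicate numbers do not pair the mice: their deviations correlated between -0.0552 and 0.146, and 1 of 6 numbers matched its own best.

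The number of called lists, 5 as reported, was 3 among the brighter probe sets, 8 with the mean of all probe sets of a gene, 0 with an estimated correlation, 1 by fry and 9 without both doubted arrays; the cause was not tested. Leaving out 1 mouse gave 4 to 7, and the replicate block 4. Without both doubted arrays, 1 of them from the mouse with almost no cerebellar signal, the cerebellar list turned to -0.30 (adjusted p = 0.0131). This is at the preset correlation, and the estimated one, 0.862, gave an adjusted p of 0.904 with all else as reported. The difference of the first principal component, -9.24, ran from -31.7 to 21.0 when 1 mouse was left out, and was 86.6 with unit variance, where the first component correlated 0.588 with the first and 0.802 with the second of the unscaled ones; signs are arbitrary and the order of components can change between fits, so these values do not follow 1 quantity. The difference of the RNA 3'/5' control probe sets, -0.0224, ran from -0.0328 to -0.00642. Of 5244 comparisons of named probe sets with an alternative, 5074 kept their side of the threshold, 64 lost a call, 106 gained one, 0 reversed and 37 had another sign. Of 1176 for lists, 1133 kept their side, 17 lost a call, 25 gained one, 1 reversed and 71 had another sign. Most that kept their side were called in neither fit, so these counts do not measure how stable the calls were. All 64 lost calls fall on the 4 probe sets called as reported, and all 17 on the 5 called lists. Signal near background limits the dim genes, whose log2 differences move with the offset.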

Other observations

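The split test of mixed changes was chosen after its count was seen.

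The mixed form of fry, which asks whether members change in either direction, passed for 17 of 42 lists, where 1 of 100 splits (the real one) gave as many and the highest other gave 15. Its lowest adjusted p were for circadian clock genes (2.21e-06) and mitochondrial ribosomal proteins and biogenesis (3.08e-05), followed by cytosolic ribosomal proteins, endothelial and mural cell markers and antioxidant genes (each 0.00052). The mixed form does not compare members with other genes, and 5345 of all 45037 probe sets had an unadjusted p under 0.05. At that level 3 of 20 circadian genes were higher and 2 lower, and of 51 mitochondrial genes 3 and 4. Of 39 ribosomal genes 0 were higher and 2 lower, of 24 endothelial and mural 2 and 1, and of 33 antioxidant 1 and 3. A low p therefore does not show that a list changed more than genes at large. Mitochondrial members named by the rule were Mrpl15 (364.5 ± 19.1 against 444 ± 47.8 at its brightest probe set, but 242.5 against 212 at 1425189_a_at, which differed the opposite way), Mrpl9 (288 ± 39.5 against 346 ± 25.6) and Mrps30 (183 ± 15.3 against 152 ± 17.0). Acta2, the smooth muscle actin of mural cells, read 484.5 ± 88.9 against 370 ± 20.8, while the transporter Slco1a4 of the endothelium read 436 ± 18.6 against 496 ± 33.7.

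Of the 107 genes with a called probe set among the brighter ones, 15 belong to a list fixed beforehand. Beside those named by the rule, these include, chosen after their values were seen, Ntrk2, the receptor of Bdnf (676 against 471, log2 difference 0.52), Klf9, a glucocorticoid-induced factor (843 against 699, 0.26), Glul, the glutamine synthetase of astrocytes (900.5 against 661, 0.43), Napb (1955 against 1669, 0.23) and Hspa5, a chaperone of the endoplasmic reticulum (136 against 189, -0.43). At their brightest probe sets Glul differed by -0.13, Napb by -0.06, Klf9 by 0.06, Hspa5 by 0.07 and Ntrk2 by 0.14. Probe sets of one gene often differed. Of the 138 called probe sets 94 had another probe set of the gene in the brighter set; for 46 of them another one had an unadjusted p under 0.05 the same way, and for 10 the opposite way. Of 250 such other probe sets 164 had the same sign. All 3 called probe sets of Tia1, an RNA-binding protein of stress granules chosen after its values were seen, were lower, by -0.30, -0.32 and -0.32.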
